A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

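RNA from 8 yeast cultures was measured, 1 array per culture: 2 cultures, titled biological replicates, of each of wild type W303, the RPL12A and RPL12B double deletion 6EA1, and 6EA1 with RPL12A or RPL12B on a high copy plasmid. Biotin-labelled cRNA was made from 10 ug of total RNA. The authors deposited 1 intensity per probe set and array, on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. The deposited intensity values had a 2% trimmed mean of 500.2 on each array, ran from 0.0214 to 8915 and had no missing values. Raw array files were not used here.

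The table held 10928 probe sets. The annotation gave 1 gene symbol for 7244 of them, several for 1, and none for 3683, which include control and reporter probe sets. Probe sets for S. cerevisiae numbered 5498 and stood for 5449 genes, and 1746 were for S. pombe. For the 47 genes with several probe sets, the probe set with the highest mean log2 signal stood for the gene, with the mean of all its probe sets as an alternative. The symbols of 12 genes were brought to their current form. Background on an array was the 95th percentile of its S. pombe signals, and a gene was tested if at least 2 arrays exceeded it, which left out 10 genes and kept 5439. No genome positions are printed, since no build was given with the arrays.

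Log2 signals were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), with a mean per group over all 8 arrays, 4 residual degrees of freedom and 3.23 prior degrees of freedom. The 6 comparisons between the 4 groups were tested 2-sided, with the Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Where both groups of a pair of comparisons share arrays, the correlation and covariance expected without any effect were taken from 100 simulations. Shifts of 38 gene lists with at least 3 tested genes were tested with camera at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Camera compares the genes of a list with the other genes tested. A further list, of plasmid genes native to yeast, had no probe set in the annotation used. RPL12A and RPL12B were left out of the lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

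The groups, comparisons, tests, gene lists, thresholds and the rule for naming genes were chosen before the data were examined. The rule named RPL12A and RPL12B, the 10 largest rises and falls in each of the first 3 comparisons and the 5 largest in the others (among genes past the threshold whose groups of arrays do not overlap), the members of the lists closest to phosphate, the stalk, Rpl12 modification, markers and mating type, and up to 4 genes of each other list. Alternatives were centring on the S. cerevisiae median, quantile normalization, a pseudocount of 16, a floor at background, no filter and a stricter one (the 99th percentile, 5427 genes), no trend, trend with robust variances, the 4 compared arrays alone, the replicate number as a block, a threshold of 0.01, a minimum of 2-fold, and leaving out each array. After the data were seen, centring on 18 hybridisation control probe sets was added, and so were the split of arrays by the signal of a 25S rRNA control as a block and a fit to the 5 arrays with a high 25S signal. The S. cerevisiae medians lay between 602 and 699, a ratio of 1.16.

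The comparison of the double deletion with the wild type was tested on simulated data with the same design and spread. Of 50 genes per size, 22% were recovered at a log2 change of 0.5, 74% at 1, 96% at 2 and 100% at 4, with 5 false calls among the unchanged genes. Comparing groups simulated without change gave 0 calls with limma. A list shifted by 0.3 was called by camera with adjusted p = 2.8e-16, and 0 other lists were called. Genes were simulated as independent of each other, so this run cannot show how often camera calls lists of correlated genes.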

Results

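Messenger RNA was measured on Affymetrix arrays in 4 groups of the yeast Saccharomyces cerevisiae, with 2 arrays per group and 8 arrays in all. The wild type was strain W303. The double deletion was strain 6EA1, which lacks RPL12A (YEL054C) and RPL12B (YDR418W), a pair of genes that encode the same protein of the large ribosomal subunit. The other groups were 6EA1 with a high copy plasmid carrying RPL12A (plus RPL12A) or RPL12B (plus RPL12B). Cells grew at 30 °C in defined medium with 2% glucose to an A600 of 0.5 to 0.6. Of 5449 genes, 5439 were tested. Of the tested genes, 99.8% to 99.9% lay above the background of each array. That background was a signal of 7.42 to 8.72 set by the probe sets for Schizosaccharomyces pombe. Tested genes had to exceed it on at least 2 arrays, so the filter fixes part of this share. Across genes, which are not independent replicates, the log2 signals of both arrays of a group correlated at r = 0.989 in the wild type, 0.985 in the double deletion, 0.972 with plus RPL12A and 0.959 with plus RPL12B. The number of arrays limits the precision. With 2 arrays against 2, an exact 2-sided test cannot go below p = 0.333, so the tests rest on limma, which shares its estimate of the spread across genes. Adjusted p values are its 2-sided values after the Benjamini-Hochberg adjustment. SD stands on n = 2 arrays per group. SE is that of limma for a log2 difference, with the spread estimated over all 8 arrays and shared across genes.

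The signals of RPL12A and RPL12B followed the genotypes. RPL12A gave 5295 ± 36.7 (SD, n = 2) in the wild type, 17.8 ± 15.5 in the double deletion, 5906 ± 246 with plus RPL12A and 11.9 ± 5.21 with plus RPL12B. RPL12B gave 6788 ± 355 in the wild type, 9.52 ± 11.1 in the double deletion, 34.3 ± 20.1 with plus RPL12A and 5957 ± 691 with plus RPL12B. The double deletion signal of each gene lay under the background on 1 of the 2 arrays, so the size of its log2 differences is uncertain. With signals under the background set to it, RPL12A fell by 8.47 in the double deletion against the wild type on the log2 scale and RPL12B fell by 9.19 (adjusted p = 0.000587 and 0.000300). Against the double deletion, plus RPL12A then raised RPL12A by 8.62 (adjusted p = 0.00252) and plus RPL12B raised RPL12B by 8.997 (adjusted p = 0.000572). Without double deletion replicate 2, the array under the background, the deposited values gave differences of -7.52 and -8.61 for the deletion and of 7.68 and 8.42 for the plasmids. On the deposited values these 4 differences were called too, that of RPL12B with plus RPL12B at an adjusted p = 0.0126 that rose above 0.05 without either wild type or either plus RPL12B array, up to 0.0858 without plus RPL12B replicate 2. Each high copy plasmid gave a signal close to that of the wild type chromosomal gene. The log2 difference from the wild type was 0.16 for RPL12A (adjusted p = 0.895) and -0.19 for RPL12B (adjusted p = 0.906). For RPL12A it was 0.25 with quantile normalization and 0.39 with hybridisation control centring, and for RPL12B 0.03 and 0.05. These signals lay near the highest signal of an array, which was between 6841 and 8915. Whether a higher mRNA level would show at such signals was not tested.

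**Figure D1:**
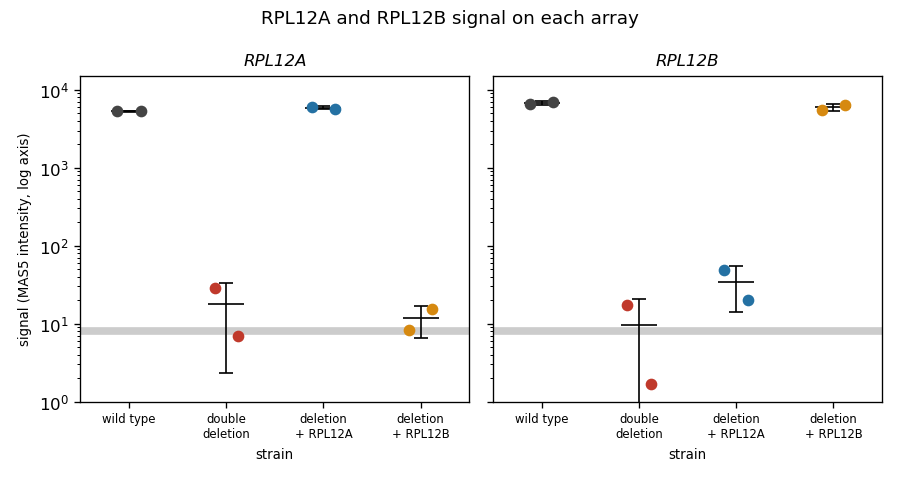
Signal of RPL12A and RPL12B (log axis, deposited scale) on each of the 8 arrays by group; points are arrays, bars with error bars the mean ± SD (n = 2, the lower end for RPL12B in the double deletion being off the axis), and the grey band the background of 7.42 to 8.72. RPL12A reached 5295 in the wild type and 5906 with plus RPL12A, against 17.8 in the double deletion and 11.9 with plus RPL12B.

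The double deletion was compared with the wild type to find the genes whose expression differs when both RPL12 genes are lost. Apart from RPL12A and RPL12B, the largest falls were in genes of phosphate and sulfate uptake. PHO84 (YML123C), the high affinity phosphate transporter, went from 2966 ± 668 (SD, n = 2) to 58.5 ± 10.2, a log2 change of -5.66 (SE 0.49, adjusted p = 0.00156). SPL2 (YHR136C), a regulator of phosphate transport, went from 610.4 ± 109 to 15.96 ± 4.28, a log2 change of -5.27 (SE 0.35, adjusted p = 0.000679). SUL1 (YBR294W), a sulfate transporter, went from 2293 ± 61.0 to 153 ± 29.5, a log2 change of -3.92 (SE 0.15, adjusted p = 0.000126). HO, the mating type switching endonuclease, changed by -3.05, HMS2 by -2.84, the zinc transporter ZRT1 by -2.54 and INO1, the enzyme that makes inositol phosphate, by -2.33. RPS22B, a gene of the small ribosomal subunit, changed by -2.10 and BAR1, the protease that degrades alpha factor, by -1.45. Both arrays of the double deletion lay beyond both wild type arrays for each gene named in this comparison.

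Of the 23 genes tested in the lists of phosphate (PHO) regulon genes, 10 fell and 4 rose. These lists were drawn up knowing that published work on these strains concerns phosphate genes, so they are not independent evidence. Besides PHO84 and SPL2, the genes that fell were the acid phosphatases PHO11 (-2.25) and PHO5 (-1.41), PHM6 (-2.17), PHM8 (-1.65), and the polyphosphate synthesis genes VTC3 (-1.12), VTC4 (-0.74), VTC1 (-0.70) and VTC2 (-0.67, and -0.41 without double deletion replicate 1). The genes that rose were PHM7 (1.77), DIA3 (1.05), GPP2 (0.66) and PHO91 (0.51), a vacuolar phosphate transporter. The PHO11 probe set is of a type that can also read a similar gene, and PHO12 has no probe set in the annotation used. Among the 8 PHO signalling genes tested, PHO80, the cyclin that represses the regulon, rose by 0.72 (0.48 with quantile normalization) and the others were not called. By list, 1 of 6 transporters, 3 of 6 phosphatases and 6 of 11 other targets were called lower (1, 3 and 7 when adjusted over the list alone). The directions of these genes were the same under the 4 scalings compared, but the calls of VTC2, VTC4, PHM7 and DIA3 did not pass under each of them. The list of other targets was called by camera (adjusted p = 0.00227, and adjusted p = 0.390 with an estimated correlation), and the lists of transporters and phosphatases (both 0.170) and of signalling genes (0.659) were not. With hybridisation control centring camera called transporters (adjusted p = 0.0280) and phosphatases (adjusted p = 0.00580). The transporter median there was 0.069, above 0, and the phosphatase median -0.40, where the median of all genes was 0.55. With an estimated correlation camera called 0 lists on the deposited scale.

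**Figure D2:**
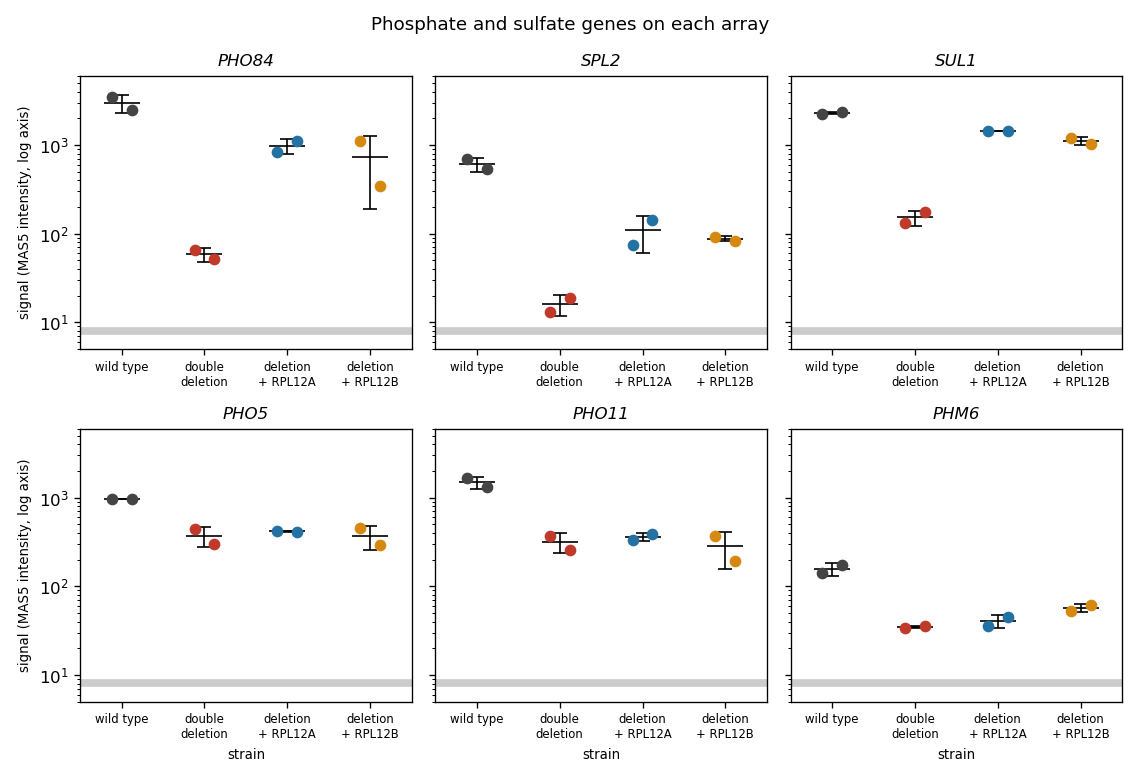
Signal of 5 phosphate regulon genes and of SUL1 (log axis, deposited scale) on each array by group; points are arrays, bars with error bars the mean ± SD (n = 2), and the grey band the background of 7.42 to 8.72. PHO84 lay at 2966 in the wild type, 58.5 in the double deletion, 981 with plus RPL12A and 725 with plus RPL12B, while PHO5 lay at 372 in the double deletion and at 416 and 370.4 with the plasmids.

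The largest rises in the double deletion were in NCA3, RTC3 and PET18. NCA3 (YJL116C), a member of the SUN family, went from 74.0 ± 0.40 (SD, n = 2) to 999 ± 88.4, a log2 change of 3.75 (SE 0.24, adjusted p = 0.000679). RTC3 (YHR087W) rose by 3.31 (SE 0.49, adjusted p = 0.00664) and PET18 (YCR020C) by 2.65 (SE 0.23, adjusted p = 0.00163). They were followed by YJL213W (2.57), LEU2 (2.44), YER039C-A (2.42), the stress gene SPI1 (2.34), the small heat shock protein gene HSP42 (2.27), IRC15 (2.20) and HVG1 (2.14). DDR2, another general stress gene, rose by 2.10. Of 7 genes used as auxotrophic markers 5 rose and 2 fell: besides LEU2, HIS3 rose by 1.90, URA3 by 1.35 and ADE2 by 0.95. The sources used here do not say which marker genes served to build the strains or which supplements each strain received. Changes of marker genes, and of genes for amino acid or pyrimidine synthesis, therefore cannot be assigned to the loss of RPL12. The call of HSP42 did not pass under each of the 4 scalings.

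**Figure D3:**
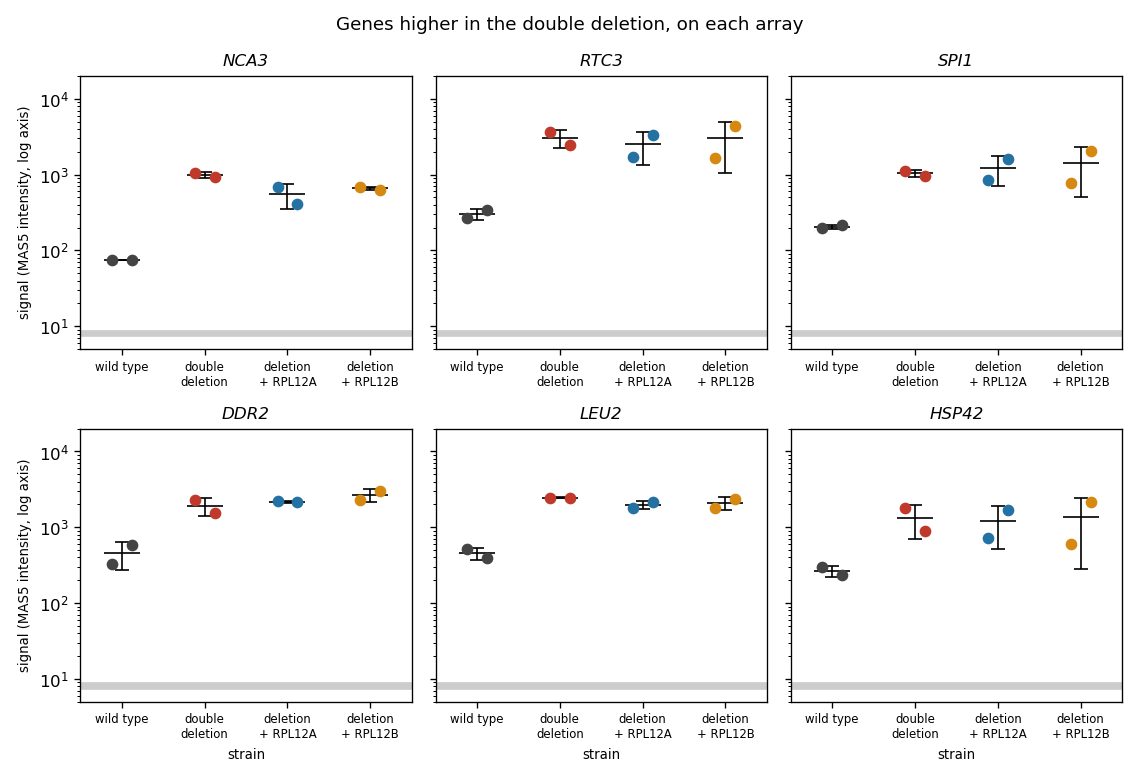
Signal of 6 genes with large rises in the double deletion (log axis, deposited scale) on each array by group; points are arrays, bars with error bars the mean ± SD (n = 2), and the grey band the background of 7.42 to 8.72. NCA3 lay at 74.0 in the wild type and 999 in the double deletion, and at 552 and 656 with the plasmids.

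Of the 5439 genes, 1109 were called higher and 661 lower in the double deletion than in the wild type (2443 had an unadjusted p under 0.05), and 266 and 44 of these differed at least 2-fold. The split between higher and lower moved with the scaling of the arrays, because the median log2 difference of all genes was 0.14 on the deposited scale, -0.06 after centring on the S. cerevisiae median, -0.0025 with quantile normalization and 0.55 with hybridisation control centring. Both centrings move all genes of a comparison by one amount, so that small differences of named genes moved the most in proportion. The counts higher and lower were 548 and 1206 after median centring, 391 and 427 with quantile normalization, and 2821 and 65 with hybridisation control centring. Under each of the 4 scalings, 289 genes were called higher and 64 lower. The hybridisation controls were lower in the double deletion arrays by a mean log2 between -0.44 (bioB) and -0.37 (bioD). Whether centring on them follows the amount of mRNA in the cells was not tested. The 25S rRNA control probe set split the arrays otherwise, with a signal of 148 on wild type replicate 2, 277 on plus RPL12A replicate 2 and 312 on plus RPL12B replicate 2 and of 2476 to 5720 on the other 5 arrays. With that split as a block 2179 genes were called, and 810 on the 5 arrays alone, which hold 1 wild type array and 1 of each plasmid strain. Without 1 array, the 1770 calls became 478 (wild type replicate 1), 256 (wild type replicate 2), 238 (double deletion replicate 1) or 1129 (double deletion replicate 2). Of the 58 genes named for this comparison, 34 kept their call without each of the 8 arrays in turn. The adjusted p went up to 0.0634 for PHO5 without wild type replicate 2, 0.0596 for PHM8 without wild type replicate 1, and, without double deletion replicate 1, to 0.0668 for ZRT1, 0.0538 for RTC3, 0.0773 for SPI1 and 0.195 for HSP42. For the rest of the genes that lost their call it went up to at most 0.188 (PHM7) without a wild type array or double deletion replicate 1.

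Ribosomal protein genes were lower in the double deletion on the deposited scale, and the sign of their medians turned with the scaling. Of the large subunit genes, without RPL12A and RPL12B, 52 of 68 were called lower (62 when adjusted over the list alone), with a median log2 of -0.30 that was -0.01 with quantile normalization and 0.10 with hybridisation control centring. Of the small subunit genes 43 of 52 were called lower (49 when adjusted over the list alone), with a median of -0.31, -0.02 and 0.10 on these scales. RPL9B (-1.002) and RPS22B (-2.10) fell under each of the 4 scalings. The camera adjusted p was 1.2e-22 and 2.8e-20 for the large and small subunit, and adjusted p = 0.434 and 0.390 with an estimated correlation. With quantile normalization camera called neither list (adjusted p = 0.498 and 0.243). With hybridisation control centring camera called both (adjusted p = 0.00502 and 0.000436), where their medians lay below that of all genes, 0.55. The 5 genes of the ribosomal stalk, which lies beside Rpl12 on the ribosome, were called lower (5 when adjusted over the list alone), with a median of -0.34. Their camera adjusted p on the deposited scale was 0.000834, and 0.435 with an estimated correlation. The stalk median was -0.07 with quantile normalization and turned to 0.06 with hybridisation control centring. Camera did not call the list on either of these scales (adjusted p = 0.275 and 0.125). Translation factors had 20 of 36 genes lower (23 when adjusted over the list alone) and ribosome biogenesis 24 of 98 (23 when adjusted over the list alone), with medians of -0.27 and -0.35. On the deposited scale the camera adjusted p was 3.2e-10 and 1.3e-12, and 0.390 and 0.561 with an estimated correlation. With hybridisation control centring the medians turned to 0.13 and 0.06 (camera adjusted p = 0.0610 and 1.0e-14), both below the 0.55 of all genes. The translation factors lost their call there. With quantile normalization the median of the translation factors was -0.05 and their call was also lost (adjusted p = 0.159). After median centring the medians of these 5 lists lay between -0.55 (ribosome biogenesis) and -0.47 (translation factors). The ribosome biogenesis median was -0.17 without double deletion replicate 1 and -0.55 without double deletion replicate 2.

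Genes for amino acid synthesis under the activator Gcn4 and for mitochondrial ribosomal proteins had lower medians under each of the 4 scalings. Of the Gcn4 list 33 of 48 genes were called lower and 1 higher (37 and 1 when adjusted over the list alone), among them ARG1 (-1.24), LYS20 (-1.05), ARO2 (-0.94) and the vitamin B6 gene SNZ1 (-0.89). Their median was -0.49, against -0.34 with quantile normalization and -0.08 with hybridisation control centring. On the deposited scale the camera adjusted p was 1.7e-17, and 0.390 with an estimated correlation. Of the mitochondrial ribosomal protein genes 42 of 68 were called lower (52 when adjusted over the list alone), MRPL13 (-0.85) among them. Their median was -0.44, against -0.58 with quantile normalization and -0.03 with hybridisation control centring. The camera adjusted p on the deposited scale was 5.8e-17, and 0.390 with an estimated correlation. General stress genes were called higher as a list, with 12 of 47 genes higher and 1 lower, also when adjusted over the list alone. Of all 5439 genes 1109 were called higher. The general stress median was 0.85 (0.75 with quantile normalization, 1.26 with hybridisation control centring). For this list the camera adjusted p on the deposited scale was 0.00101, and 0.688 with an estimated correlation. In all, camera called 17 of 38 lists, 1 higher and 16 lower, and 7 of them also with quantile normalization in the same direction. With an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05), and fry called 12, of which 10 were camera calls in the same direction.

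**Figure D4:**
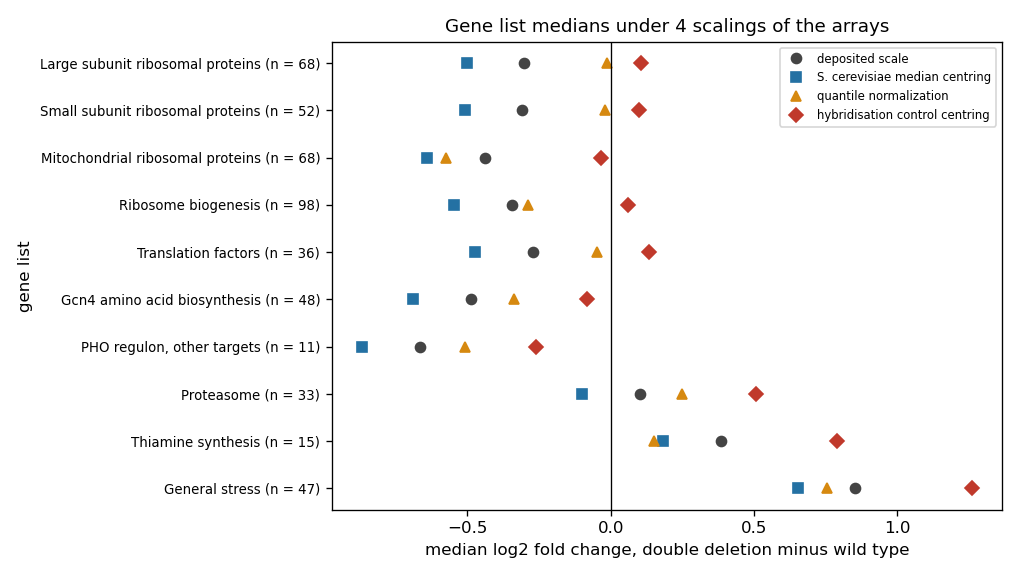
Median log2 difference between the double deletion and the wild type (horizontal axis) of 10 gene lists under 4 scalings of the arrays; each point is the median of a list's tested genes. Both lists of cytosolic ribosomal protein genes (-0.30 and -0.31 on the deposited scale), ribosome biogenesis and translation factors turned above 0 with hybridisation control centring, the proteasome turned below 0 with median centring, and general stress genes lay above 0 on each scale (0.85 deposited).

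Plus RPL12A was compared with the double deletion to find the genes that change when one of the lost genes is given back. Besides RPL12A, the genes that rose most were PHO84, SUL1, SPL2 and QDR2. PHO84 rose to 981 ± 195 (SD, n = 2), a log2 change of 4.06 (SE 0.49, adjusted p = 0.0322), and SPL2 to 109 ± 48.5, a change of 2.72 (SE 0.35, adjusted p = 0.0424). SUL1 rose to 1441 ± 10.1, a change of 3.25 (SE 0.15, adjusted p = 0.000482). QDR2, a multidrug transporter gene, rose by 2.39, the vitamin B6 genes SNO1 by 1.60 and SNZ1 by 1.37, RPS22B by 1.21, ARG1 by 0.72 and SAM4, a gene of methionine recycling, by 0.67. In the double deletion against the wild type SNZ1 had changed by -0.89, less than it rose here. QDR2 had changed there by -2.26 to -1.95 with 1 array left out at a time. The differences of other PHO genes from the double deletion were 0.19 for PHO5 (95% interval -0.39 to 0.76), 0.21 for PHO11 (-0.54 to 0.97), 0.21 for PHM6 (-0.34 to 0.76) and 0.22 for VTC3 (-0.18 to 0.62), and these were not called. Such intervals are not adjusted for the number of genes. Those of VTC2 (0.45, 0.06 to 0.84), PHO80 (-0.46, -0.75 to -0.17) and PHO81 (-0.47, -0.91 to -0.02) left out 0, also without a call. In the PHO lists, which are not independent evidence, 1 of 6 transporters and 1 of 11 other targets were called higher (1 and 1 when adjusted over the list alone). Limma called 12 genes higher and 0 lower (386 and 466 at an unadjusted p under 0.05), and 6 of the 12 were called under each of the 4 scalings: RPL12A, PHO84, SUL1, QDR2, SNO1 and SNZ1. With the replicate number as a block more genes were called, some of them lower, as given below with the other settings. Without 1 array the 12 became 5 (wild type replicate 1, wild type replicate 2 or plus RPL12A replicate 1) or 4 (double deletion replicate 1 or plus RPL12A replicate 2). RPL12A, SUL1, QDR2 and SNZ1 kept their call each time, while the adjusted p of SPL2 went up to 0.412 without double deletion replicate 1. Without plus RPL12A replicate 2 it went up to 0.253 for PHO84 and SAM4, 0.0892 for SNO1, 0.204 for RPS22B and 0.432 for ARG1. With the 25S split as a block 11 genes were called, and 5 on the 5 arrays with a high 25S signal.

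The Gcn4 list was higher with plus RPL12A than in the double deletion under each of the 4 scalings. Its median log2 was 0.36 (0.25 with quantile normalization, 0.19 with hybridisation control centring), and 5 of 48 genes were called higher (38 when adjusted over the list alone; camera adjusted p = 4.1e-33, adjusted p = 0.216 with an estimated correlation). The median of the large subunit ribosomal protein genes was 0.18 (camera adjusted p = 1.6e-23, adjusted p = 0.345 with an estimated correlation). It was -0.01 with quantile normalization, where camera did not call the list (adjusted p = 0.579). It was 0.0069 with hybridisation control centring, 0.30 after median centring and 0.10 without double deletion replicate 1. That of the small subunit genes was 0.19, but 0.00016 with quantile normalization, where camera did not call them (adjusted p = 0.9994), 0.019 with hybridisation control centring and 0.31 after median centring. Of these 52 genes 1 was called higher (17 when adjusted over the list alone; camera adjusted p = 1.5e-20, adjusted p = 0.310 with an estimated correlation). Camera called 19 of 38 lists higher and 1 lower, against 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 0 with fry (12 at an unadjusted p under 0.05).

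Plus RPL12B was compared with the double deletion for the same question. Besides RPL12B, the genes that rose were SUL1, to 1116 ± 122 (SD, n = 2) with a log2 change of 2.88 (SE 0.15, adjusted p = 0.00115), QDR2 by 2.47, SNO1 by 1.76, SNZ1 by 1.37 and SAM4 by 0.70. PHO84 reached 725 ± 535 with a log2 difference of 3.42 (SE 0.49) and SPL2 reached 87.4 ± 5.77 with a difference of 2.48 (SE 0.35). Neither passed the test after adjustment (adjusted p = 0.100 and 0.0985), although the 95% intervals were 2.27 to 4.56 and 1.66 to 3.30. Leaving out 1 array at a time gave differences of 2.58 to 4.25 for PHO84 and 2.20 to 2.76 for SPL2. PHM6 differed by 0.70 (95% interval 0.15 to 1.26) and PHO80 by -0.42 (-0.71 to -0.13), without a call. PHO5 gave -0.02 (-0.59 to 0.56), PHO11 -0.22 (-0.98 to 0.54) and VTC3 0.10 (-0.30 to 0.50). Limma called 6 genes higher and 0 lower (181 and 211 at an unadjusted p under 0.05), 5 of them under each of the 4 scalings. More were called with the replicate number as a block, as given below. SUL1, QDR2 and SNZ1 kept their call without each array in turn, SNO1 lost it without double deletion replicate 2 (adjusted p = 0.0551), and SAM4 lost it without any 1 of the 8. The Gcn4 list was higher again, with a median of 0.31 (0.25 with quantile normalization, 0.14 with hybridisation control centring) and 2 of 48 genes called (27 when adjusted over the list alone; camera adjusted p = 6.0e-35, adjusted p = 0.390 with an estimated correlation). The medians of the large and small subunit ribosomal protein genes were both 0.09. Their camera adjusted p was 2.0e-12 and 1.7e-10, and 0.450 for both with an estimated correlation. The medians turned to -0.0038 and -0.0048 with quantile normalization and to -0.07 for both with hybridisation control centring, against 0.18 for both after median centring. Camera called neither list with quantile normalization (adjusted p = 0.998 for both) or with hybridisation control centring (adjusted p = 0.782 and 0.692). Without double deletion replicate 1 or 2 or plus RPL12B replicate 1 or 2 the large subunit median was 0.029, 0.15, 0.14 or 0.036, and without double deletion replicate 1 or 2 or plus RPL12B replicate 2 the small subunit median was 0.030, 0.14 or 0.026. Camera called 17 of 38 lists higher and 2 lower, against 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 0 with fry (3 at an unadjusted p under 0.05). With the 25S split as a block 9 genes were called, and 7 on the 5 arrays with a high 25S signal.

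Both plasmid strains were also compared with the wild type, to see which differences of the double deletion were left. Among the PHO genes called lower with both plasmids, SPL2 was lower by a log2 of -2.55 with plus RPL12A and -2.79 with plus RPL12B, PHO11 by -2.04 and -2.47, PHM6 by -1.96 and -1.47, PHM8 by -1.76 and -1.54 and PHO5 by -1.23 and -1.43, with adjusted p up to 0.0451 for PHO5 with plus RPL12A. PHO84 was called lower with plus RPL12B (-2.24, adjusted p = 0.0380, and -1.41 without plus RPL12B replicate 2) and gave -1.59 with plus RPL12A (adjusted p = 0.107). SUL1 was called lower with plus RPL12B (-1.04, adjusted p = 0.0184) and gave -0.67 with plus RPL12A (adjusted p = 0.0599). HMS2 (-2.31 and -2.20), BAR1 (-1.44 and -1.45) and the mitochondrial ribosomal protein gene MRPS35 (-0.98 and -0.98) were also lower with plus RPL12A and plus RPL12B. Of the 266 genes higher by at least 2-fold in the double deletion, 70 were still called higher in both plasmid strains, against the same wild type arrays that chose them. Those named here had log2 differences from the wild type of 2.995 and 3.17 for RTC3, 2.85 and 3.15 for NCA3, 2.5 and 2.62 for SPI1, 2.31 and 2.59 for DDR2, 2.14 and 2.20 for LEU2, 1.88 and 1.98 for PET18, 1.60 and 1.42 for URA3, 1.51 and 1.29 for the citrate synthase gene CIT3 and 1.29 and 1.58 for HIS3. With plus RPL12A, NCA3, LEU2 and URA3 kept their call without each array in turn, and with plus RPL12B so did RPL12A, NCA3, YJL213W, LEU2 and URA3. For the other genes called here the adjusted p rose above 0.05 without at least 1 array, up to 0.219 for PHO5 with plus RPL12A without wild type replicate 2 and to 0.180 for PHO84 with plus RPL12B without wild type replicate 1. The calls of PHO5, RTC3, SPI1 and HIS3 with plus RPL12A, and of PHO84 with plus RPL12B, did not pass under each of the 4 scalings.

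Against the wild type, 121 genes were called higher and 95 lower with plus RPL12A, and 304 and 212 with plus RPL12B. Of these, 116 higher genes were shared (6.76 if independent) and 90 lower genes (3.70 if independent), and both comparisons use the same 2 wild type arrays, which cannot be split, so part of the excess may come from them. Across 5437 genes the log2 differences correlated at 0.945, against 0.50 in simulated data without effects, and their covariance was 0.170 against 0.0262. The simulation takes arrays as independent, so variation common to arrays of both strains is not in it. With quantile normalization the counts were 47 and 33 with plus RPL12A and 96 and 104 with plus RPL12B, and with hybridisation control centring 609 and 24, and 961 and 31. Without 1 array, the 216 calls with plus RPL12A became 13 (wild type replicate 1), 12 (wild type replicate 2), 52 (either double deletion array), 13 (plus RPL12A replicate 1) or 15 (plus RPL12A replicate 2). The 516 calls with plus RPL12B became 21 and 14 without wild type replicate 1 and 2, 232 and 243 without the double deletion arrays, 233 and 237 without the plus RPL12A arrays, and 263 and 33 without plus RPL12B replicate 1 and 2. With the 25S split as a block 728 and 1219 genes were called. Mitochondrial ribosomal protein genes had a median of -0.42 with plus RPL12A, with 13 of 68 called lower (41 when adjusted over the list alone; camera adjusted p = 4.4e-21, adjusted p = 0.519 with an estimated correlation), and of -0.45 with plus RPL12B, with 26 lower (47 when adjusted over the list alone; camera adjusted p = 1.2e-21, adjusted p = 0.475 with an estimated correlation). With hybridisation control centring these medians were -0.19 and -0.21. General stress genes had a median of 0.95 with plus RPL12A, with 5 of 47 higher (7 when adjusted over the list alone; camera adjusted p = 1.5e-08, adjusted p = 0.859 with an estimated correlation), and of 1.06 with plus RPL12B, with 8 higher (16 when adjusted over the list alone; camera adjusted p = 6.5e-08, adjusted p = 0.632 with an estimated correlation). The stress median with plus RPL12A was 1.43 without its replicate 1 and 0.56 without its replicate 2, and with plus RPL12B 1.76 and 0.38 without its replicates 1 and 2. Replicate 2 of each plasmid strain also had the low 25S signal, and on the 5 arrays with a high 25S signal, 1 array against 1, the medians were 0.59 and 0.37. The size of this rise moved with these arrays. Camera called 14 of 38 lists with plus RPL12A and 18 with plus RPL12B, and with an estimated correlation 0 in each (2 in each at an unadjusted p under 0.05), while fry called 4 in each.

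Of the 1770 genes called between the double deletion and the wild type, 12 were called in the opposite direction by adding RPL12A, 6 by adding RPL12B and 5 by both. At an unadjusted p under 0.05 they were 653 with RPL12A and 287 with RPL12B, and of the 310 genes at least 2-fold different 292 and 273 had an estimate in the opposite direction. These comparisons use the same 2 double deletion arrays, whose chance errors by themselves push the estimates in opposite directions, so part of each count may come from them. With the replicate number as a block, more genes were called in the opposite direction, as given below with the other settings. The labels do not say whether arrays with the same number were paired. Still called against the wild type, in the direction of the double deletion, were 211 with plus RPL12A, 495 with plus RPL12B and 201 in both. The count in both was 75 with quantile normalization and 240 after median centring, and it moved with other settings too, as given below. Of the 310 genes at least 2-fold different in the double deletion, 91 were still called in both plasmid strains, 70 higher and 21 lower. The same 2 wild type arrays both chose the genes and entered these tests. Chance errors there push both differences the same way, so part of each count of genes still called may come from them. Changes on deletion and on adding RPL12A correlated at -0.657 across genes, and with RPL12B at -0.565, where the shared double deletion arrays alone gave -0.50 in simulated data. Their covariances were -0.106 and -0.0836, against -0.0264 and -0.0263 in simulated data. The changes on adding RPL12A and on adding RPL12B correlated at 0.877, against 0.50 in simulated data, with a covariance of 0.0732 against 0.0264. The simulated values again take arrays as independent, and correlated variation between arrays of different strains would move them. Deviations of arrays with the same replicate number did correlate between plus RPL12A and plus RPL12B, at 0.79 across genes. So the value without effects may differ from 0.50.

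Plus RPL12B was compared with plus RPL12A to find genes that depend on which copy is present. RPL12A was the gene called, lower by a log2 of -9.03 with plus RPL12B (adjusted p = 0.0061, and 0.0728 without plus RPL12A replicate 1). RPL12B gave a difference of 7.57 (95% interval 5.34 to 9.81, adjusted p = 0.216, and 0.00186 with a floor at background). The differences of PHO84, SPL2 and SUL1 were not called either, so the calls of PHO84 and SPL2 against the double deletion are not shown to differ between the plasmid strains. Limma called 0 genes higher and 1 lower (27 and 66 at an unadjusted p under 0.05). Without 1 array the count was 0 (either wild type or either plus RPL12A array), 2 (either double deletion array) or 1. Camera called 12 of 38 lists lower, 6 of them also with quantile normalization, against 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 0 with fry (2 at an unadjusted p under 0.05).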

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

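The search of probe sets without a listed gene was chosen after the data were seen. RPL12A differed between the plasmid strains by a log2 of -9.03 (plus RPL12B minus plus RPL12A), with signals of 11.9 and 5906, which follows from the gene that each plasmid carries.

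Probe sets without a listed gene took no part in the comparisons. Among these 3683, a pair stood at least 10 times above both the wild type signal and the background on all 6 arrays of the deletion strains. Reporter probe set 1 had a lowest signal of 5482 in the deletion strains and a highest of 7608, against 0.657 and 5.89 in the wild type. Reporter probe set 2 had a lowest signal of 107 and a highest of 298, against 7.25 and 7.56 in the wild type. Both belong to the 47 reporter probe sets of the array, and the sequence they read is not given in the sources used here. The signal was also present in the double deletion, for which no plasmid is named.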

How the results depend on the processing

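Centring on hybridisation controls and both settings built on the 25S control were chosen after the data were seen. Of 2640 values of called genes named in the text (110 results, 24 settings), 2260 stayed past the threshold in the same direction, 380 fell short of it and none turned; 38 of these results stayed past it in every setting. Of 437 values of called list shifts, 393 stayed, 34 fell short and 10 turned. Signal over background limits RPL12A and RPL12B where they are deleted. Camera has no robust option, so list shifts have no value under trend with robust variances. Where 1 array is left out, the lone array left in its group is assumed to vary like the other groups. The cause was not tested for the changes below, except that a stricter threshold and a minimum fold lower a count by construction.

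With quantile normalization the counts were 818 genes for the double deletion (680 shared with the 1770), 80 and 200 for plus RPL12A and plus RPL12B against the wild type, 75 still different in both plasmid strains, and 11 lists each for the double deletion, plus RPL12A and plus RPL12B against the double deletion. RPL12B with plus RPL12B against the wild type turned to 0.026. Ribosomal protein medians against the double deletion turned to -0.011 (large subunit, plus RPL12A), -0.0038 (large subunit, plus RPL12B) and -0.0048 (small subunit, plus RPL12B). With hybridisation control centring the counts were 2886 (1174 shared), 7 for plus RPL12A against the double deletion with 6 of them reversals, 633 and 992 against the wild type, 566 in both, and 12 lists for plus RPL12B against the double deletion. RPL12B turned to 0.049 as above, and for the double deletion the medians turned to 0.10 (large subunit), 0.10 (small subunit), 0.059 (ribosome biogenesis), 0.13 (translation factors), 0.064 (stalk) and 0.069 (phosphate transporters). With plus RPL12B against the double deletion the large subunit turned to -0.072 and the small to -0.073. With S. cerevisiae median centring PHO signalling turned to -0.015 and the proteasome to -0.10.

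Plus RPL12B against plus RPL12A gave 2 genes with a pseudocount of 16 and 2 with a floor at background. With no trend, plus RPL12A gave 5 genes against the double deletion (5 reversals) and 103 against the wild type, and 98 stayed different in both. With only the 4 arrays compared, the count for the double deletion against the wild type rose to 2292 (1466 higher, 826 lower), and the others were 5 and 0 against the double deletion (5 and 0 reversals; limma at the same threshold), 77 and 32 against the wild type and 30 in both, and the rise of RPL12B (10.09) had adjusted p = 0.103. With a minimum of 2-fold they were 310, 61 and 107 against the wild type, 6 and 3 reversals and 53 in both. With a threshold of 0.01 they were 449, 13 and 27 against the wild type, 6 with plus RPL12A against the double deletion (6 reversals) and 13 in both, and RPL12B (10.09) fell short. With a replicate block the counts were 79 (68 higher, 11 lower) and 17 (16 higher, 1 lower) against the double deletion (75 and 17 reversals), 719 and 1219 against the wild type and 625 in both. Deviations of arrays with the same replicate number correlated across genes at 0.33, 0.41, 0.34, 0.29, 0.05 and 0.79 between pairs of groups. With the 25S split as a block, 728 and 1219 genes differed from the wild type and 620 in both. The 5 arrays with a high 25S signal hold 1 array of each group but the double deletion, so the spread comes from that pair, and fewer calls there say nothing about the strains. On them the counts were 810, 22 and 23 against the wild type, 5 with plus RPL12A against the double deletion (5 reversals), 0 between the plasmid strains and 19 in both; there PHO84 turned to 0.39 and SPL2 to 0.30 between the plasmid strains. With an estimated correlation camera called 0, 0 and 0 lists, and fry 0 and 0 for the plasmid strains against the double deletion.

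Leaving out 1 array gave 238 to 1965 genes for the double deletion, 4 to 10 and 4 to 6 for plus RPL12A and plus RPL12B against it (4 to 10 and 3 to 6 reversals), 12 to 281 and 14 to 263 against the wild type, 12 to 148 in both and 0 to 2 between the plasmid strains. The rise of RPL12B was 8.42 to 11.8 and called in 4 of 8 fits. Against the double deletion, PHO5 ran from -0.086 to 0.46 and PHO11 from -0.050 to 0.48 with plus RPL12A, and RPL12A from -1.35 to 0.71 with plus RPL12B. Between the plasmid strains PHO84 ran from -1.48 to 0.18 and SPL2 from -0.71 to 0.23.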

Other observations

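Of 15 thiamine genes 7 rose in the double deletion against the wild type, also when adjusted over the list alone, among them PET18 (2.65), THI22 (1.42), PDC5 (1.07) and THI4 (1.04, and 0.58 with quantile normalization, where its call was lost at an adjusted p = 0.0514). The thiamine median was 0.38, 0.18 after median centring, 0.15 with quantile normalization and 0.79 with hybridisation control centring, and camera called the list after median centring (adjusted p = 0.0223) and not on the deposited scale (0.0651, adjusted p = 0.688 with an estimated correlation). Of 33 proteasome genes 10 rose, also when adjusted over the list alone, among them PRE5 (0.57) and RPN5 (0.49), where 1109 of all 5439 genes rose. The proteasome median was 0.10, -0.10 after median centring, 0.25 with quantile normalization and 0.51 with hybridisation control centring, and camera called the list on the last 2 scales (adjusted p = 1.6e-08 and 0.000184) and not on the deposited scale (0.0817, adjusted p = 0.806 with an estimated correlation). The calls of THI22, THI4, PDC5 and RPN5 were lost without at least 1 array, with an adjusted p up to 0.0840 for PDC5 without wild type replicate 2.

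Iron regulon genes rose in 7 of 26 cases and fell in 1, ISU2 (1.47) and FIT1 (1.10, and 0.63 with quantile normalization) among those that rose (camera adjusted p = 0.528). Of all 5439 genes 1109 rose. Of 18 sporulation genes 3 rose and 2 fell, also when adjusted over the list alone, among them REC8 (1.76) and SPO11 (-1.48), and of 12 pyrimidine genes 1 rose, the uracil permease gene FUR4 (1.18), and 3 fell, FUR1 (-1.41) among them (1 and 4 when adjusted over the list alone); camera called neither list (adjusted p = 0.791 and 0.0737). Without 1 array the adjusted p went up to 0.0655 for REC8, 0.0611 for FUR4, 0.0787 for FIT1, 0.0537 for ISU2 and 0.134 for SAG1 (each without double deletion replicate 1) and to 0.0547 for SPO11 (wild type replicate 2). Among mating type genes BAR1 changed by -1.45 and SAG1, the agglutinin of alpha cells, rose by 1.09 (0.63 with quantile normalization, where its call was lost at an adjusted p = 0.112), and neither mating type list was called (camera adjusted p = 0.110 and 0.790). The list of enzymes that modify Rpl12, with 3 tested genes, was not called (camera adjusted p = 0.437).

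The tests below were all chosen after the results were seen. The lower medians of ribosomal protein genes in the double deletion were set against a bias of high signals that the array scaling leaves, using 10000 random lists with like signals. For cytosolic ribosomal proteins 15.84% of the random lists had a lower median than the list (-0.30, matched median -0.29), so such a bias may account for the fall. The genes drawn from left out only the ribosomal protein genes, so translation factors, which were also lower, stayed among them. The match therefore cannot tell such a bias from a fall shared by these genes. For mitochondrial ribosomal proteins (-0.44, matched 0.17) and the Gcn4 list (-0.49, matched -0.23) 0% of the lists lay below, which argues against that bias as the whole of these falls. No biological explanation was tested.

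The fall of PHO84 and SPL2 was set against a strain difference that a plasmid copy of RPL12 leaves as it is. The rise on adding back RPL12A or RPL12B had a 95% interval whose smaller lower bound was 2.27 for PHO84 and 1.66 for SPL2, which argues against such a difference as the whole of the fall. The intervals rest on the same double deletion arrays that made these genes the largest falls, which may enlarge the rise. With plus RPL12B neither rise passed the test after adjustment. Of the 8 other PHO regulon genes that fell, 6 were still called lower than the wild type in both plasmid strains. The same wild type arrays both chose these genes and entered this test, so chance errors there may add to the 6. Within that limit the calls argue against a loss that a plasmid copy of RPL12 fully undoes. VTC2 and VTC4 stay open there, and so does an effect of the plasmid itself, since no strain with an empty plasmid was measured. For the PHO genes that stayed low, the calls cannot tell a strain difference other than RPL12 from a loss that a plasmid copy undoes only in part.

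Chromosome II genes were higher on the array of plus RPL12A replicate 1, and less so on that of replicate 2 (0.09, with 0.02 and 0.10 on the arms). The median log2 difference of 385 genes from the wild type, centred on all genes, was 0.22, with 73.5% above 0, where the largest other median among 128 pairs of array and chromosome was 0.12. All of the random lists with like signals (100%) lay below it, which argues against a bias that follows the level of the signal. The shift was 0.205 on the left arm and 0.23 on the right. Single arms reached as much elsewhere, up to 0.265 for the 23 genes of the right arm of chromosome I on double deletion replicate 1, but the smaller shift of both arms was at most 0.11 elsewhere, so an extra copy of the chromosome in part of the culture is a candidate explanation and not shown.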
